A study of Rattus norvegicus with 6 samples.

How the data were processed

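Total RNA of 6 samples of rat dermal fibroblasts was labelled with the dye Cy3 and hybridised to one-colour Agilent rat gene expression arrays, 1 array per sample, per the labels' protocols. Samples were grouped by their titles into control lentivirus (n = 3) and lnc-URIDS shRNA lentivirus (n = 3), both at a multiplicity of infection of 10 with 2 µg/mL puromycin for 48 h. Replicate numbers came from the titles.

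The authors deposited the scanner output of each array, in which the intensity of every spot is given on a linear scale, per the file headers. The processed intensity had been background-subtracted, spatially detrended and floored by Agilent Feature Extraction (version 11.0.1.1 per the file headers, 11.0.0.1 per the submitters' processing notes), with no normalization between arrays. The raw median intensity of the spot and of its local background were deposited beside it, together with flags for outlier, saturated and well above background spots. Each array held 44254 spots, of which 42877 were gene spots and the rest control spots, which were left out. Per array 386 to 513 gene spots carried an outlier flag and were left out too; 0 were saturated. Between 68.8% and 74.1% of the 30367 probes were well above background on an array, and the median local background was 20 to 26 units against a median processed signal of 215 to 237.

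The log2 of the processed signal minus the array's 75th percentile of log2 signal was used, so that values are relative to that percentile. Spots of a probe were averaged (1390 probes were printed 10 times). A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 20773 probes. Probes were named through their RefSeq accession, without version, with a table of the GRCr8 assembly used for names only, because the array was designed on another assembly; 18005 probes matched and stood for 15168 symbols, and the rest kept the name in the files. The brightest probe stood for a gene. This gave 18461 features, of which 10751 were named genes and 7710 unnamed transcripts; 5 had a missing value on an array. Of 1815 genes with more than 1 tested probe, 571 had probes of opposite sign, and in 3 both signs had an unadjusted p under 0.05. Where a group was not well above background on any array, the fold is a lower bound: the mean of the bright group against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array.

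Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05; fold changes are knockdown minus control on the log2 scale, with moderated standard errors. The 32 gene lists were tested with camera (preset correlation 0.01, at least 5 tested members, adjusted over the lists). Before the data were examined, the following were fixed: the groups, the tests, the lists, the alternatives, and the rule for the genes named. That rule took Plod1 (and lnc-URIDS if a probe carried its name), the 10 genes with the largest folds in each direction among those that passed with non-overlapping groups, in each list the 3 members with the largest change among those that passed or else the member with the smallest p, and the housekeeping genes as a range. As no gene passed, its second part named none; further genes were chosen after values were seen, by the same rule at an unadjusted p under 0.005 and, within lists, among the members of largest change at an unadjusted p under 0.05, plus a few well-known members.

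The scan identifiers of the file headers placed control 1, control 2, knockdown 2 and knockdown 3 on slide 1 and control 3 and knockdown 1 on slide 2. Each slide held equal numbers of both groups, so a block on slide leaves the fold and alters its error; slide was fitted as a block and values were taken within each slide; slide 2, with 1 array per group, allows no test.

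The alternatives were quantile normalization, centring on the median of the tested probes, normexp background correction with an offset of 50 (with the 75th percentile or quantile scaling), no filter or a filter on all 6 arrays, the mean of a gene's probes, an intensity trend, array quality weights (gene-by-gene method, since the default did not converge), replicate and slide blocks, leaving out each array, limma's treat against a 1.2-fold change, unadjusted p with a 2-fold change, and, for lists, camera with an estimated correlation and fry. Normexp was run on the spot's median intensity; a mean intensity was not used here. Fits with replicates 1 and 2 only, with slide 1 only, and without control 1, control 3 and knockdown 1 were added after the data were seen.

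The limma and camera steps were tested on simulated data with the features' own means and spreads, without slide effects or correlation between genes, for knockdown against control over 18456 features. In each of 10 runs, 50 features were changed at each fold size. The test called 62.0% of them at 1.5-fold, 80.4% at 2-fold, 96.0% at 4-fold and 98.0% at 8-fold. It also called 12.3 other features per run, which can include members of the contractile list shifted in the same runs. That list, shifted by a log2 value of 0.2, was called in all 10 runs. Figures were drawn with matplotlib 3.10.9.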

Results

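Gene expression was measured in cultured rat dermal fibroblasts, the cells that make the collagen matrix of the skin. The cells carried a lentivirus that expresses a short hairpin RNA (shRNA) against the long non-coding RNA lnc-URIDS (knockdown, n = 3) or a control lentivirus (n = 3). The virus was given at a multiplicity of infection of 10, and puromycin, which kills cells without the viral cassette, was present at 2 µg/mL for 48 h. Each sample was hybridised to 1 one-colour Agilent array with 30367 gene probes, of which 20898 to 22489 were well above background on each array. The 75th percentile of the processed signal lay between 1493 and 1609 on the 6 arrays, and no spot was saturated. The number of arrays limits the precision. The labels do not say whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

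The first question was whether the knockdown altered the transcript it targets and Plod1, a lysyl hydroxylase that modifies collagen and was fixed as a gene of interest before the data were examined. No value is given for lnc-URIDS, because none of the probes named here carries that name, so the knockdown itself was not checked. Plod1 signal was nearly equal in the groups, with a log2 fold change (knockdown minus control) of -0.01 ± 0.08 (SE, n = 3 per group; limma adjusted p = 0.975). Its 95% confidence interval ran from 0.859-fold to 1.14-fold, and its sign turned when arrays were centred on the median of the tested probes. With slide as a block, which leaves a fold as it is because each slide holds equal numbers of both groups, the Plod1 value was also -0.01 (adjusted p = 0.951, and 0.657 to 0.994 over all alternatives); within slide 1 it was 0.05 and within slide 2 it was -0.14. The Plod1 log2 signals relative to the array's 75th percentile were 2.19, 2.28 and 2.19 in controls 1, 2 and 3, and 2.05, 2.35 and 2.22 in knockdown 1, 2 and 3. The other lysyl hydroxylases, chosen after values were seen, had log2 fold changes of 0.26 ± 0.10 (Plod2) and 0.04 ± 0.10 (Plod3), with limma adjusted p of 0.322 and 0.911.

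The second question was which genes differed between knockdown and control fibroblasts. No gene or unnamed transcript passed the limma test at an adjusted p under 0.05, in either direction or at any fold, among 18461 features, of which 10751 were named genes. The smallest adjusted p was 0.0825, for Scg2, the secretogranin of neuroendocrine secretory granules, whose signal was 2.58-fold that of controls (log2 fold change 1.37 ± 0.08, SE, n = 3 per group) and which was well above background on 1 of 3 control arrays and on 3 of 3 knockdown arrays. Its log2 fold change was 1.37 with slide as a block (adjusted p = 0.223), 1.36 within slide 1 and 1.39 within slide 2; over all alternatives the adjusted p ran from 0.0299 to 0.602, and Scg2 passed in 2 of 19. With a normexp background its log2 fold change was 0.67, and 0.36 with quantile scaling added. With slide as a block, 0 genes passed, and 1154 features had higher and 1609 lower means at an unadjusted p under 0.05. At an unadjusted p under 0.05, 1091 features had higher and 1524 had lower means in knockdown, of which 25 and 19 differed at least 2-fold. Chance alone would give 923 features at that threshold if the arrays were independent. Other splits of the 6 arrays into 3 and 3 gave 151 to 3298 features. The groups did not overlap in 21.7% of the features, against 10% by chance for independent arrays. Since the samples may not be independent, these comparisons cannot show an excess over chance. The share of higher means among the features at an unadjusted p under 0.05 was 41.7% with the 75th percentile scaling, 57.0% with centring on the median, and 52.1% with a normexp background.

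Other genes are named by their values, after the values were seen, from those with the largest folds among non-overlapping genes with an unadjusted limma p under 0.005; none of them passed the adjusted test with arrays weighted equally. With array quality weights, which put most weight on control 3 and knockdown 3, 47 of 113 named genes passed, among them Scg2 and every gene of this paragraph. Over all 18461 features, these weights called 291 higher and 448 lower. Most named genes were chosen for a small p or a large change on these same arrays, so their passing is no independent support. On the higher side, the microtubule regulator Stmn2 had a log2 fold change of 2.55 ± 0.49 (SE, n = 3 per group) and the scavenger receptor Olr1 one of 1.55 ± 0.28. The lactate receptor Hcar1 was not well above background on any control array. On the processed signal it was at least 1.81-fold higher in knockdown (limma adjusted p = 0.196), a bound that does not hold with a normexp background. The skeletal myosin heavy chain genes Myh2 and Myh1 had log2 fold changes of 1.74 ± 0.32 and 1.14 ± 0.17, and Myh8 was 2.30-fold as bright in knockdown; Myh2 was well above background on 2 of 3 control arrays. The sequences of these myosins are closely related, so a probe of 1 of them can also read another. Ppp1r14a, an inhibitor of myosin phosphatase, had 1.06 ± 0.21, the actin nucleation subunit gene Arpc3 had 0.93 ± 0.14, and the kinase gene Mapkapk3 had 0.92 ± 0.15. On the lower side, the matricellular protein gene Sparcl1 had a log2 fold change of -1.89 ± 0.34 and the gelatinase gene Mmp9 -1.57 ± 0.32. The stem cell factor gene Kitlg had -1.49 ± 0.33 on its brightest probe and -0.17 ± 0.21 on a second probe. The transcription factor gene Dmrt2 had -1.30 ± 0.16, the potassium channel regulator gene Abcc9 -1.14 ± 0.10, the decarboxylase gene Ddc -0.95 ± 0.10, the amine oxidase gene Aoc3 -0.87 ± 0.10, and the ubiquitin ligase gene Rnf144a -0.86 ± 0.15. C1qtnf7, well above background on 1 of 3 knockdown arrays, had -1.55 ± 0.34. Mmp9 and Ddc were well above background on 2 of 3 knockdown arrays. Many of these changes were smaller with a normexp background. Its offset of 50 units shrinks the folds of dim probes by construction. With the normexp background Sparcl1 had -0.39, Mmp9 -0.17, Abcc9 -0.24, Aoc3 -0.40, Rnf144a -0.33, Myh2 0.79 and Hcar1 0.70 (0.34 with quantile scaling added). The signs for C1qtnf7 and Ddc turned (0.05 and 0.12), but not with quantile scaling added (-0.28 and -0.19). The cause of the turn was not tested.

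**Figure D1:**
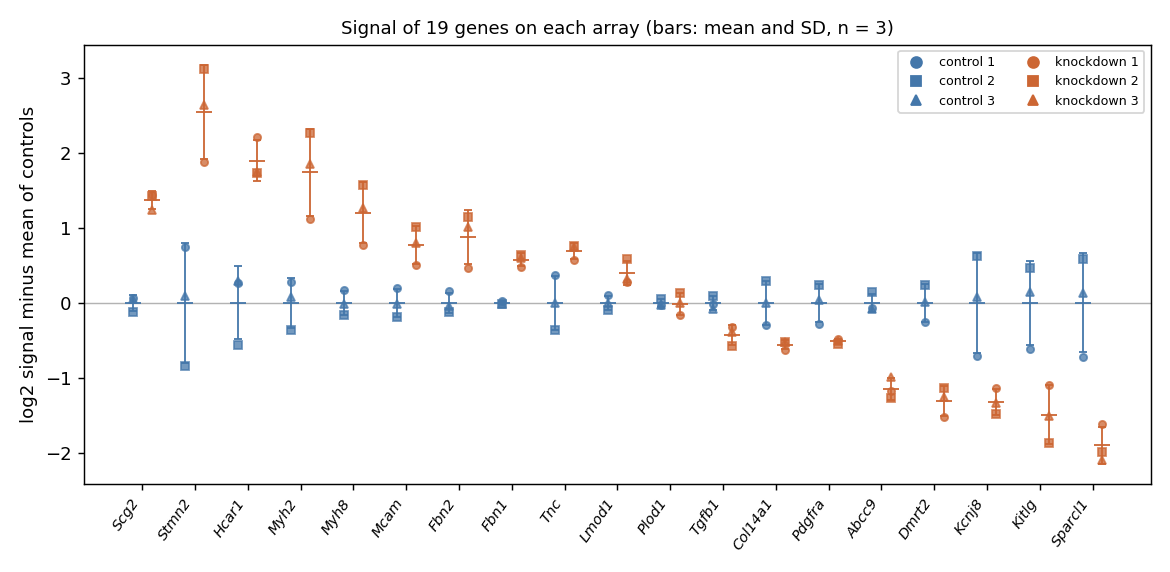
Log2 signal of 19 genes on each of the 6 arrays, minus the mean of the 3 control arrays (y axis); points are arrays, and bars give the mean and SD of each group (n = 3). Stmn2 and Hcar1 lie highest in knockdown and Sparcl1 lowest, and Plod1 lies at -0.01. Hcar1 was not well above background on any control array, so its height rests on dim control values. None of the genes passed the adjusted test with arrays weighted equally.

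The third question was whether groups of genes fixed before the data were examined moved together, tested for 32 lists with camera at a preset correlation of 0.01. The contractile and myofibroblast list rose as a set at that correlation (adjusted p = 0.0109), but it did not pass at an estimated correlation (adjusted p = 0.809) or with fry (adjusted p = 0.349). Of its 17 measured genes, 12 had higher and 5 lower means in knockdown, with a median log2 fold change of 0.19 (a fold of 1.14). No member passed over all genes, and 4 passed when adjusted over the list alone. The member with the smallest p was Lmod1, a smooth muscle actin nucleator, with 0.40 ± 0.10 (SE, n = 3 per group) on its brightest probe and 0.08 ± 0.08 on the second. Myh11, the smooth muscle myosin heavy chain gene, had 0.55 ± 0.15, Pdlim7, which tethers proteins to actin, had 0.45 ± 0.12, and the myosin light chain kinase gene Mylk had 0.41 ± 0.15; their second probes had 0.18 ± 0.06, 0.28 ± 0.14 and 0.28 ± 0.19. Acta2, which encodes smooth muscle actin and marks myofibroblasts, had 0.10 ± 0.05, and Tagln 0.19 ± 0.07. Des, which encodes desmin, had -0.20 ± 0.08 (0.15 with normexp, and -0.07 with quantile scaling added). The list's median relative to each gene's mean was 0.03 in both control 1 and knockdown 1, -0.23 and -0.12 in controls 2 and 3, and 0.14 and 0.13 in knockdown 2 and 3. Without control 2 the adjusted p was 0.0532, and over all alternatives it ran from 0.000708 to 0.809. With the replicate number as a block the list did not pass (adjusted p = 0.0618). With slide as a block the median was 0.19 (adjusted p = 0.0164); on slide 1 (2 control and 2 knockdown arrays) it was 0.23 and on slide 2 (1 of each) 0.12.

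Markers of other contractile cells moved in several directions beside this list. Of the 9 measured pericyte and vascular smooth muscle markers, 4 passed when adjusted over the list alone and none over all genes. Among them Abcc9 and Kcnj8, which form the potassium channel of pericytes, had log2 fold changes of -1.14 ± 0.10 and -1.32 ± 0.33, and Mcam, an adhesion molecule of mural cells, had 0.77 ± 0.15; Myh11, also in the contractile list, was the other that passed. With a normexp background Abcc9 and Kcnj8 had -0.24 and -0.50. That list did not pass the set test (camera adjusted p = 0.751). Its median was -0.08, with 0.12 under normexp and -0.03 with quantile scaling added. Of 12 skeletal muscle markers, Myh8 (2.30-fold) and Myh3 passed over the list alone and none over all genes. Myh3 had a log2 fold change of 0.89 ± 0.16, and 0.46 ± 0.72 on its second probe. The actin genes Acta1 and Actc1 had 0.05 ± 0.08 and -0.04 ± 0.17. The slow troponin gene Tnnt1 had -0.18 ± 0.08 (0.15 with normexp, and -0.06 with quantile scaling added). The skeletal muscle list did not pass (median 0.06, adjusted p = 0.228).

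The oxidative stress and NRF2 target list fell as a set at the preset correlation (adjusted p = 0.0333), but it did not pass at an estimated correlation (adjusted p = 0.809), with fry (adjusted p = 0.240) or with slide as a block (adjusted p = 0.0767). Of its 26 measured genes, 20 had lower and 6 higher means in knockdown, with a median log2 fold change of -0.09 (a fold of 0.940). None of its members passed over all genes or when adjusted over the list alone. The member with the smallest p was the heme oxygenase gene Hmox1, with -0.35 ± 0.07 (SE, n = 3 per group), beside the quinone reductase gene Nqo1 with -0.57 ± 0.23 and the catalase gene Cat with -0.31 ± 0.08. With slide as a block the median stayed at -0.09; within slide 1 and slide 2 the medians were -0.12 and -0.04. The list also did not pass with the replicate number as a block (adjusted p = 0.0834), without control 2 (adjusted p = 0.230), without knockdown 1 (adjusted p = 0.0881) or without knockdown 2 (adjusted p = 0.0718), and over all alternatives the adjusted p ran from 2.57e-06 to 0.809.

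Among the fibrillar collagens, the main product of these cells, Col1a1, Col1a2 and Col3a1 gave nearly equal signals. They had log2 fold changes of -0.02 ± 0.06, 0.06 ± 0.07 and 0.04 ± 0.09 (SE, n = 3 per group), and Col1a1 had -0.09 ± 0.14 on its second probe. The fibrillar Col5a3 had -0.31 ± 0.10 (limma adjusted p = 0.271). The fibronectin gene Fn1 had 0.01 ± 0.04, and -0.13 ± 0.06 on its second probe. The signs for Col1a1 and Fn1 turned with other scalings. Of the 11 measured collagen chains, 8 had lower and 3 higher means (median -0.02, adjusted p = 0.575), and none passed over all genes or over the list alone. The smallest p was that of Col14a1, a fibril-associated collagen, with -0.56 ± 0.15. The 28 collagen processing and crosslinking enzymes had a median of 0.01 (adjusted p = 0.619), and the smallest p was that of PCOLCE2, an enhancer of procollagen cleavage, with 1.28 ± 0.31 (0.56 with normexp, and 0.23 with quantile scaling added) and a signal well above background on 1 of 3 control arrays. Of the 27 matrix glycoproteins and proteoglycans, 6 passed when adjusted over the list alone and none over all genes. Fbn1, the microfibril gene fibrillin, had 0.57 ± 0.06, its relative Fbn2 had 0.87 ± 0.19, and the tenascin gene Tnc had 0.69 ± 0.19, against -0.64 ± 0.15 for the cartilage proteoglycan gene Acan. That list did not pass as a set (median 0.09, adjusted p = 0.174). The 21 matrix proteases and inhibitors also did not pass (median -0.04, adjusted p = 0.188); Mmp9 had the smallest p, with -1.57 ± 0.32.

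Fibroblast identity markers had lower means in 14 of 18 measured genes, with a median of -0.10 (adjusted p = 0.174). No member passed over all genes, and 4 passed when adjusted over the list alone. Of these, the mesenchymal transcription factor genes Twist1 and Twist2 had log2 fold changes of -0.24 ± 0.04 and -0.24 ± 0.06 (SE, n = 3 per group), the growth factor receptor gene Pdgfra had -0.51 ± 0.13, and the integrin gene Itga8 was higher, with 0.30 ± 0.07 and with 0.06 ± 0.14 on its second probe. Prrx1 had -0.70 ± 0.22 and did not pass. In the TGF-beta list of 22 genes (median -0.07, adjusted p = 0.469), 2 passed over the list alone; Id2, an inhibitor of differentiation factors, had the smallest p with -0.40 ± 0.07, and the ligand genes Tgfb1 and Bmp4 had -0.43 ± 0.09 and -0.45 ± 0.11. The 15 measured YAP target genes went both ways (median 0.08, adjusted p = 0.751), and 6 passed over the list alone, among them the tissue factor gene F3 with 0.62 ± 0.10, the ectonucleotidase gene Nt5e with -0.37 ± 0.05 (-0.052 with normexp) and the receptor kinase gene Axl with -0.38 ± 0.10. The 18 Wnt genes had a median of 0.02 (adjusted p = 0.458), with Ccn4 at 0.27 ± 0.05.

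Of the 24 interferon and antiviral genes measured, which respond to double-stranded RNA and virus, 18 had lower means in knockdown (median -0.11, adjusted p = 0.0603), and none passed over all genes or over the list alone. The peptide transporter gene Tap1 had the smallest p, with a log2 fold change of -0.41 ± 0.09 (SE, n = 3 per group). Its sign and that of the list's median turned with a normexp background (0.02 and 0.02). They did not turn with quantile scaling added (-0.18 and -0.08). In the cytokine and NF-kB list (23 genes, median -0.04, adjusted p = 0.448) the chemokine gene Ccl5 had the smallest p, with -0.33 ± 0.06. The Ccl5 sign turned with normexp (0.045), but not with quantile scaling added (-0.14). Of 31 genes of the endoplasmic reticulum and integrated stress response, 21 had lower means (median -0.07, adjusted p = 0.188); Phgdh, of serine synthesis, had the smallest p with 0.27 ± 0.06, and the chaperone gene Calr had -0.32 ± 0.08. Of 26 glycolysis and hypoxia genes, 19 had lower means (median -0.08, adjusted p = 0.188) and 6 passed over the list alone. The pyruvate kinase gene Pkm had -0.38 ± 0.08 and the vessel growth factor gene Vegfa 0.30 ± 0.05 on its brightest probe; the other 3 Vegfa probes ranged from -0.06 to 0.18. The 27 growth and angiogenic factors (median 0.01, adjusted p = 0.751) hold Vegfa, which passed over that list alone, and Kitlg.

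The lists of the cell cycle and of basic cell functions did not pass with the main settings. The 24 mitosis genes had a median log2 fold change of 0.03 (adjusted p = 0.458; Cenpf -0.11 ± 0.05, SE, n = 3 per group), and the 29 DNA replication genes one of 0.03 (adjusted p = 0.317; Gins1 0.18 ± 0.05). The 23 p53 target genes had -0.02 (adjusted p = 0.905; Gadd45a 0.21 ± 0.06) and the 19 senescence genes -0.07 (adjusted p = 0.419; Bmi1 -0.12 ± 0.05). Among the 25 immediate early genes (median 0.06, adjusted p = 0.254), Klf4 passed over the list alone, with 0.49 ± 0.07. The 29 cholesterol genes had 0.02 (adjusted p = 0.751), the 7 genes of the small RNA machinery 0.07 (adjusted p = 0.188; Xpo5 0.14 ± 0.05, and -0.067 ± 0.074 on its second probe), the 31 oxidative phosphorylation genes -0.01 (adjusted p = 0.979; Uqcrb 0.12 ± 0.05) and the 33 cytosolic ribosomal proteins 0.01 (adjusted p = 0.362; Rpl23 0.12 ± 0.05). The 15 housekeeping reference genes ranged from -0.17 (Gapdh, -0.17 ± 0.04) to 0.18 (Tfrc, and -0.08 on its second probe) with a median of -0.02 (adjusted p = 0.619).

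Markers of other cell types had low or few measured signals. Medians were -0.05 for 7 keratinocyte and epithelial markers (adjusted p = 0.751; Krt18 0.89 ± 0.52, SE, n = 3 per group), 0.02 for 6 endothelial markers (adjusted p = 0.902; Cdh5 -0.06 ± 0.10) and 0.01 for 13 leukocyte and macrophage markers (adjusted p = 0.812; Coro1a 0.64 ± 0.23). The 6 adipocyte markers had -0.03 (adjusted p = 0.751; Pnpla2 0.12 ± 0.06) and the 6 Schwann cell and melanocyte markers -0.07 (adjusted p = 0.905; Prx -0.23 ± 0.06). With a normexp background the keratinocyte, adipocyte and Schwann cell medians turned to 0.25, 0.05 and 0.18, Cdh5 turned to 0.04, and Prx to 0.0091. With quantile scaling added, these medians were 0.0029, -0.03 and -0.02, Cdh5 had -0.02 and Prx -0.13. The set test pointed up while median and mean lay below 0 for the p53 and oxidative phosphorylation lists, while the median alone lay below 0 for keratinocyte markers, and while the mean alone did (-0.04) for growth factors.

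**Figure D2:**
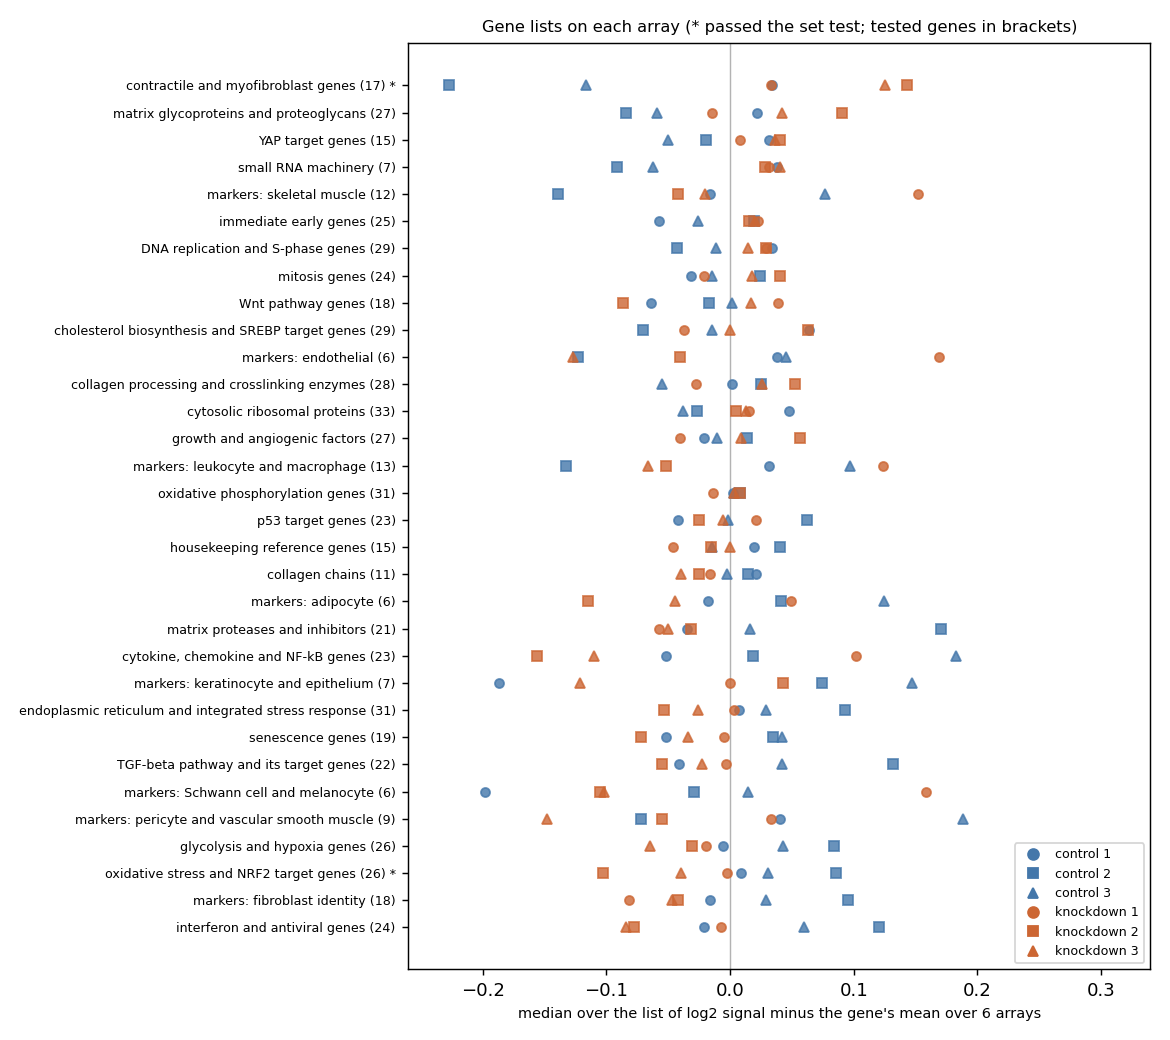
Median over each gene list's tested genes of the log2 signal minus the gene's mean over the 6 arrays (x axis), for 32 lists (y axis); points are arrays and asterisks mark the 2 lists that passed camera at the preset correlation. In the contractile list control 1 and knockdown 1 both lie at 0.03, and knockdown 2 and 3 lie at 0.14 and 0.13.

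Liver transcripts differed between arrays of the same group. The processed signal of Pzp, a plasma protease inhibitor of the liver, was 288 in control 1, 384 in control 3 and 333 in knockdown 1, against 25.1 in control 2, 26.0 in knockdown 2 and 22.0 in knockdown 3. Albumin (Alb) gave 715, 427 and 1090 in controls 1, 2 and 3 and 844, 415 and 398 in knockdown 1, 2 and 3. Over a list of 42 liver transcripts, written after this was seen, the median differences in log2 signal were 1.30 between control 1 and control 2, 1.19 between control 3 and control 2, 1.07 between knockdown 1 and knockdown 2, and 1.19 between knockdown 1 and knockdown 3. The bright arrays were controls 1 and 3 but only knockdown 1, so the groups are not balanced in these transcripts. The median knockdown minus control difference in log2 signal of that list was -0.10, with members from -1.19 (Cyp3a2) to 0.62 (Fgb). Pzp, outside that list, had -1.24.

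**Figure D3:**
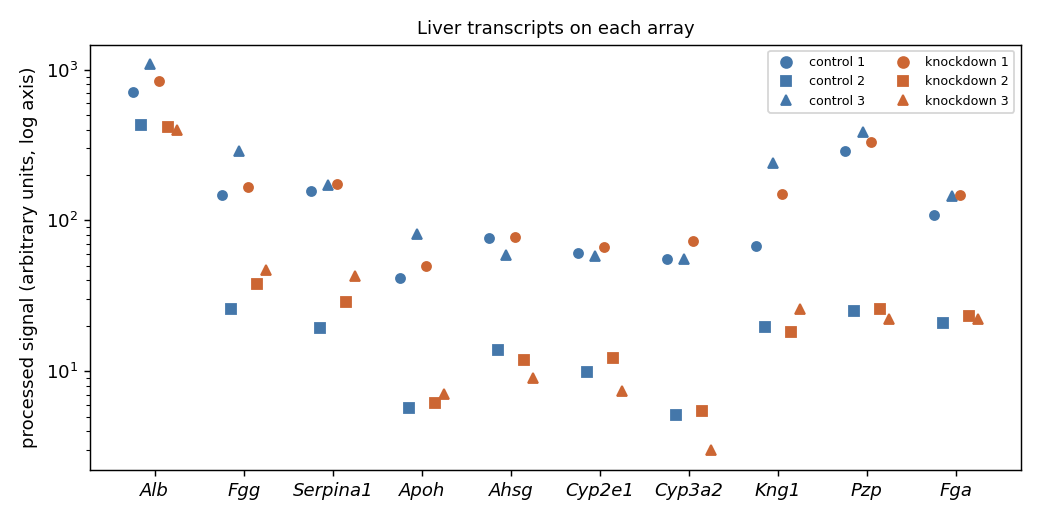
Processed signal (arbitrary units, log axis) of 10 liver transcripts (x axis) on each of the 6 arrays; points are arrays. For Pzp, control 1, control 3 and knockdown 1 lie between 288 and 384, and the other arrays between 22.0 and 26.0.

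Replicate 3 was the middle array of its group more often than replicates 1 and 2. Over 17940 features well above background on all arrays it was the middle array in 51.1% (control) and 54.7% (knockdown), against 33.3% by chance. Among the 5877 of these that were brighter on average than the array's 75th percentile the shares were 55.1% and 59.1%. With replicates 1 and 2 only, limma called 2 features higher and 4 lower at an adjusted p under 0.05, each well above background on 2 of the 6 arrays and so outside the 18461 features tested on all arrays, and the contractile list had a median of 0.20 (adjusted p = 0.0843).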

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

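The fits with replicates 1 and 2 only, with slide 1 only and without control 1, control 3 and knockdown 1 were chosen after seeing the data. The last holds 1 control array, so its spread comes from knockdown 2 and 3 alone and its gene and list counts decide nothing. No gene passed an adjusted p under 0.05 with quantile normalization, normexp with either scaling, no filter or the filter on all 6 arrays, the mean of a gene's probes, an intensity trend, the slide block or treat. Centring on the median called 1 gene higher, Scg2, by at least 2-fold. Array quality weights called 291 higher and 448 lower, 17 and 20 of them at least 2-fold; the weights were 1.87 for control 3 and 3.74 for knockdown 3 against 0.462 to 1.16 for the others, so the arrays between the other replicates carried the fit. Leaving out 1 array called 0 to 2 genes higher and 0 to 3 lower, with the same ranges at 2-fold: 2 lower without control 1 (Dpyd, Duoxa2), 3 lower without control 3 (Vom2r31 and 2 unnamed), 2 higher without knockdown 1 (Btnl2 and an unnamed one), 1 higher without knockdown 3 (C5ar1). Replicates 1 and 2 only called 2 higher (C5ar1, Cela1) and 4 lower (Vom2r31 and 3 unnamed), and slide 1 alone 5 higher (Btnl2, Dsg3, Or7g16 and 2 unnamed) and 2 lower (both unnamed), all at least 2-fold. These genes, chosen after their values were seen, make 13 features with the fits on fewer arrays; 0 of them were among the features tested on all arrays, since each was well above background on 2 arrays and the filter asks for fewer arrays when arrays are left out. An unadjusted p under 0.05 with at least 2-fold gave 25 higher and 19 lower. At an unadjusted p alone, the counts ran from 566 to 2062 higher and from 335 to 3134 lower.

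The lists that passed numbered 11 with normexp, 0 with the replicate block, 1 with the slide block, 1 with replicates 1 and 2 only, 4 without control 1, control 3 and knockdown 1, 0 with an estimated correlation and 0 with fry. Leaving out 1 array gave 0 to 6, with 6 without control 1, 0 without control 2 and 1 without knockdown 2. The contractile list had a median between 0.13 and 0.33 over its 22 alternatives and passed in 17, with adjusted p from 0.000708 to 0.809. The oxidative stress list ran from -0.16 to -0.07 and passed in 14, with adjusted p from 2.57e-06 to 0.809. These ranges and tallies include the fit with 1 control array, which gave the medians of 0.33 and -0.16. Leaving out 1 array, the medians ran from 0.13 to 0.25 (contractile) and from -0.11 to -0.07 (oxidative stress). Some lists that failed with the main settings passed in 1 to 3 of 22 alternatives, counting the fit with 1 control array. Matrix proteases and interferon genes passed in 3, and matrix glycoproteins and ribosomal proteins in 2. Collagen chains, TGF-beta, endoplasmic reticulum stress, glycolysis, small RNA, oxidative phosphorylation, housekeeping and fibroblast identity lists passed in 1. The cytosolic ribosomal proteins turned from a median of 0.011 to -0.016 (adjusted p = 0.0346) with normexp; the cause was not tested. Plod1 ran from -0.08 to 0.06 and passed in none of its alternatives.

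The numbers do not pair the samples: the correlations of same-numbered deviations were 0.10, 0.26 and -0.29. The replicate block gave 0 genes higher and 0 lower (848 and 1432 at an unadjusted p under 0.05). Dim probes limit what can be seen: many dim genes named here had a smaller change or a turned sign with normexp, and a probe near background can have a wide spread without it.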

Other observations

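The tests in this part were chosen after the result was seen, except the count of genes over other splits of the arrays, whose prediction was written before.

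Il1rl1, Cx3cl1 and Serpine2 were named after it was seen that they differ among the control arrays. Il1rl1, the receptor of interleukin-33, had log2 signals relative to the array's 75th percentile of 1.53, 3.67 and 3.12 in controls 1, 2 and 3, and 1.21, 1.70 and 1.45 in knockdown 1, 2 and 3 (log2 fold change -1.32 ± 0.55, SE, n = 3 per group; limma adjusted p = 0.363), and its second probe had -0.87 ± 0.34. The fractalkine gene Cx3cl1 had -2.24, -1.08 and -1.54 in the controls and -2.71, -2.39 and -2.59 in knockdown. Serpine2, a protease inhibitor, had -1.10, 0.12 and -0.36 in the controls and -1.28, -1.28 and -1.30 in knockdown. In each of these 3 genes control 1 was the control array nearest to knockdown and control 2 the farthest. The peptide hormone gene Adm had a log2 fold change of -0.67 ± 0.19 and did not pass the adjusted test.

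With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes at a limma adjusted p under 0.05 (2615 at an unadjusted p under 0.05), and the highest of the other splits gave 31, so 10 of the 10 splits gave as many. At an unadjusted p under 0.05, 2 of the 10 splits gave as many genes as the real one, and the highest other gave 3298. For the gene lists, 8 of the 10 splits gave as many lists as the real 2, and the highest other gave 8 lists; in that split, control 1, knockdown 2 and knockdown 3 against the rest, the contractile list had a smaller unadjusted p (2.34e-06) than in the real split (0.000341). The split with 31 genes puts control 1, control 3 and knockdown 1 on one side, which crosses both groups and points to a structure of the samples; this side holds both arrays of slide 2, and with slide as a block that split gave 7 genes, the highest split 18 (control 1, control 2 and knockdown 2 against the rest) and the real one 0. At an unadjusted p under 0.05 with that block the real split gave 2763 and the highest other 2600.

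Liver transcripts such as Pzp and Apoh were several-fold brighter in control 1, control 3 and knockdown 1. Others were not. The transferrin gene Tf had signals of 379, 388 and 382 there, against 575, 617 and 524 in control 2, knockdown 2 and knockdown 3. Ttr differed little, with 332, 302 and 357 on these 3 arrays against 351, 283 and 289. A trace of liver RNA in these 3 libraries is a candidate explanation: 34 of 42 textbook liver transcripts were brighter both in control 1 than control 2 and in knockdown 1 than knockdown 2, and the liver list had medians of 1.07 to 1.30 between bright and dim arrays of a group, against -0.07 to 0.85 for lists of kidney, striated muscle, brain, pancreas and gut, and blood (pancreas and gut 0.85 between knockdown 1 and knockdown 3, blood 0.63 between knockdown 1 and knockdown 2). A higher background or scaling of these arrays is argued against, since the largest of 10000 random lists of the same brightness reached 0.27 between control 1 and control 2, 0.40 between control 3 and control 2, and 0.33 between knockdown 1 and knockdown 2. A slide effect is argued against for control 1 by the liver list's median of 1.30 over control 2, which shares slide 1, but control 3 and knockdown 1 are the arrays of slide 2, so for them it stays open (1.07 between knockdown 1 and knockdown 2). At which step such RNA entered stays open, and no biological explanation was tested.

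Replicate 3 of both groups may hold RNA of replicates 1 and 2 mixed in equal parts: in bright genes, of 60 choices of an array and 2 others, knockdown 3 as an equal mixture of knockdown 1 and 2 had the smallest median error (0.0185 log2, 23 features differing by over 0.7) and control 3 of control 1 and 2 the next (0.0531, 32 features), so the worse rank was 2. Without the brightness cut, the equal mixture had the smaller error in control (0.136 against 0.198 for the midpoint on the log scale, 561 features differing by over 0.7) but the larger in knockdown (0.307 against 0.261, 549 features, with a best share of 0.75 for knockdown 2), which keeps this open. Mixing after the liver transcripts entered is argued against for knockdown 3, whose 42 liver transcripts lay off the mixture by a median of -0.72 (log2), just past their median absolute deviation of 0.71, with 39 on that side, and stays open for control 3, where the median was 0.32 with a median absolute deviation of 0.70. A gradient of cell states with both replicates midway cannot be told apart from earlier mixing: the midpoint on the log scale had a larger error in bright genes of knockdown (0.0712), but shares of cells in different states would also add on the linear scale. No biological explanation was tested; if replicate 3 is a mixture, the samples of a group are not independent.

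The contractile genes rose as a set at the preset correlation but did not pass at an estimated one (adjusted p = 0.809) or with fry (adjusted p = 0.349). More skeletal muscle cells in knockdown cultures stay open: 10 skeletal muscle markers other than the myosins had a median log2 fold change of 0.055 ± 0.061 against the contractile list's 0.19, but 0.13 ± 0.06 against 0.15 with a normexp background. More pericytes or vascular smooth muscle cells stay open too: Abcc9 (-1.14) lay opposite to Mcam (0.77), but with a normexp background Abcc9 had -0.24 ± 0.23. Each slide held equal numbers of both groups, so a shared slide effect cancels by design and was not tested. An effect of the knockdown stays open and untested, as does a difference between cultures, since the list's median was 0.03 in both knockdown 1 and control 1.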
